A study of Mus musculus with 6 samples.

How the data were processed

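Ribosome-depleted RNA of 6 cultures was sequenced on an Illumina NovaSeq, per the labels' protocols. Per the submitters' processing notes, STAR 2.6.1a, featureCounts and DESeq2 1.18.1 were used with the mm10 build; parameters, strand setting and annotation are not given in the sources used here. The authors deposited 2 tables of 55450 genes each, 1 per construct. Per the file headers, each holds the authors' DESeq2 mean, log2 fold change with its standard error, Wald statistic (a score), p-value and adjusted p-value, beside 4 library columns of normalized counts, a signal never below 0. The deposited log2 fold changes run from construct to empty vector, so a gene higher with a construct is negative there. All fold changes here run the other way.

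Each deposited library column consisted of whole reads divided by 1 factor, so reads were recovered by dividing by the smallest value above 0. All values above 0, 100% in each column, came out whole within 0.001 of a read, and a library present in both tables gave the same reads in each. All 55450 gene IDs were found in GENCODE vM21, which gave symbols, positions and gene types.

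Library columns carry no group, replicate or donor label. The libraries present in both tables were taken as empty vector, since both constructs were compared with it, and the others as the construct their table is named for. The distinction of ADAR2 WT from ADAR2 E396A therefore rests on the names of the deposited tables. The labels describe 2 donor mice, each construct being compared with empty-vector cells of the same donor, and a donor block was fixed as the main design before the data were examined. Which libraries share a donor was worked out afterwards: DESeq2 was refitted to the recovered reads under each possible pairing, and the pairing was taken that returned the authors' deposited Wald statistics. With it the largest difference over 28601 genes was 0 to 4 decimals for ADAR2 WT and over 28872 genes 0.0001 for ADAR2 E396A. Without a donor term the largest differences were 6.67 and 2.03, and with donors crossed 13.8 and 6.08. The pairing was thus read from the authors' deposited statistics, not from a label, and was settled before the numbers of genes passing here were seen. The calls depend on it, and values without it are given beside them. Which labelled replicate is donor A is not known.

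Because the deposited values are normalized, limma 3.58.1 in R 4.3.3 was used in place of the count test foreseen for raw counts. The count test, edgeR, was run on the recovered reads as an alternative, with median-of-ratios factors as planned and with TMM as added after the data were examined. Recovered reads were scaled over all 6 libraries by median-of-ratios factors, filtered with edgeR's filterByExpr, and tested as log2 of normalized count plus a pseudocount of 1, with group and donor as terms and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates changes of low genes. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01 and with an estimated correlation, and with fry. With an estimated correlation camera relies on the few residual degrees of freedom that 6 libraries leave. Hardly any list could pass that version, so a call lost there does not by itself show that correlated genes made it. Of 25 lists fixed before the data were examined, 22 had enough measured members. The lists were: ADAR family, Th17, Th1 and cytotoxic, Th2, Treg, interferon-stimulated, recoding targets of editing, double-stranded RNA binding and paraspeckle, cell cycle, TGF-beta, IL-6 and STAT3, T cell activation, naive and memory, glycolysis and hypoxia, cholesterol, stress response, p53, mitochondrial, ribosomal protein, and markers of B, myeloid, CD8 and NK, gamma-delta T, erythroid and stromal cells.

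Genes named were fixed by rule beforehand. They were Adarb1, Adar, Il17a, Il17f, Foxp3, Ifng and Tbx21, 1 further gene that is not reported here, up to 10 highest and 10 lowest passing genes per comparison with a mean of at least 50 normalized counts (predicted genes, clones and antigen receptor variable segments left out), and up to 4 passing members of each list. Other genes named, among them Cd8a, Cd8b1, Gm7860, n-R5-8s1 and Gm26917, were chosen after their values were seen.

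Alternatives were edgeR 4.0.16, DESeq2 1.42.0, other scalings, filters, pseudocounts and thresholds, the 4 libraries of a comparison alone, and each library left out. The edgeR test with TMM called 136, 3 and 10 genes in the 3 comparisons, against 122, 2 and 10. The test was checked on simulated counts for ADAR2 WT against empty vector, with 200 of 14958 genes changed in each of 3 runs. The changed genes were drawn only among those with a mean of at least 50 reads, so recovery of lower genes was not measured. It recovered 92.3% of genes changed 2-fold (277) and 70.3% of those changed 1.5-fold (211), with 43 false calls over the runs. In 50 simulations with no change, ADAR2 WT against empty vector gave 2.76 calls on average and at most 15. All these simulations draw genes independently, and so leave out variation that moves many genes of a library together.

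Depth was 19094778 and 19674041 reads for empty vector, 20127063 and 16496328 for ADAR2 WT, and 19483096 and 21897166 for ADAR2 E396A (donors A and B). The gene Gm26917 took 8.68% to 10.5% of the reads of a library. Genes with near-identical copies, such as Gm7860 and other pseudogenes, and overlapping genes may share reads and are uncertain. Reads, and with them editing and vector sequence, were not analysed here.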

Results

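RNA-seq libraries were made from mouse CD4 T cells that had been activated, driven toward the Th17 state with TGF-beta and IL-6, and transduced with a murine stem cell virus (MSCV) retrovirus. The cells were collected at 72 h. The 6 libraries formed 3 groups of 2: empty vector, ADAR2 WT, and ADAR2 E396A, an enzymatically dead form. ADAR2, encoded by Adarb1, is an enzyme that deaminates adenosine to inosine in double-stranded RNA. The cells came from 2 mice, called donors A and B here, and each donor gave 1 library per group (n = 2 per group). Which libraries share a donor was read from the authors' deposited statistics and not from a label. Reads assigned to genes ranged from 16496328 in the ADAR2 WT library of donor B to 21897166 in the ADAR2 E396A library of donor B. Editing was not measured here, only the abundance of transcripts.

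The first question was whether the constructs were expressed. Adarb1 (ENSMUSG00000020262.15, chromosome 10, 77290726 to 77418270, mm10) was at 3672 and 3332 normalized counts in the empty-vector libraries of donors A and B. It was at 18422 and 18999 with ADAR2 WT and at 15644 and 14920 with ADAR2 E396A. Adarb1 rose by 2.42 on the log2 scale with ADAR2 WT (SE 0.07, limma adjusted p = 2.21e-06) and by 2.13 with ADAR2 E396A (SE 0.07, limma adjusted p = 6.48e-06). The difference between the constructs, 0.29 (SE 0.07), did not pass after adjustment (limma adjusted p = 0.161). Reads of the transgene and of the endogenous gene cannot be separated in these counts. Adar, which encodes the related deaminase ADAR1, had log2 fold changes of 0.25 with ADAR2 WT (limma adjusted p = 0.141) and 0.07 with ADAR2 E396A (limma adjusted p = 0.999).

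**Figure D1:**
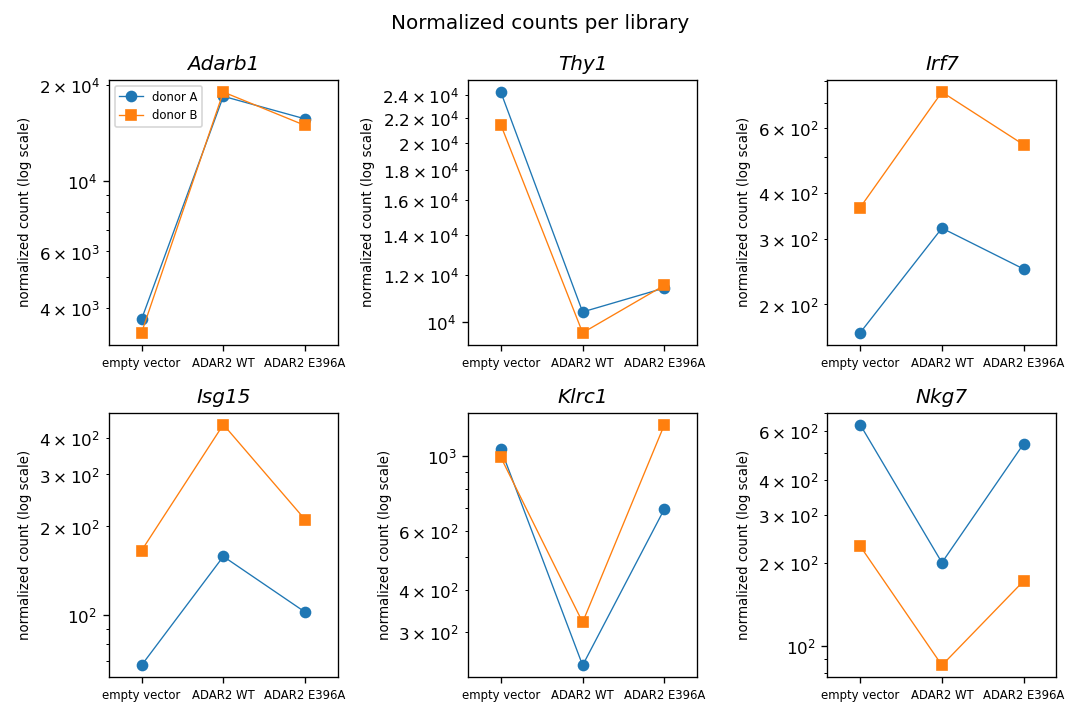
Normalized counts (y axis, log scale) of 6 genes in each of the 6 libraries, with groups on the x axis and lines joining the libraries of 1 donor. Adarb1 lies at 3332 to 3672 in the empty-vector libraries and at 14920 to 18999 in the others, and Klrc1 and Nkg7 are lowest with ADAR2 WT in both donors.

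ADAR2 WT was compared with the empty vector to find what the active enzyme changed. The killer cell receptor genes Klrc1, Klrd1 and Klrk1 and the cytotoxic granule gene Nkg7 were lower, and 10 of 33 measured interferon-stimulated genes were higher. Klrd1 and Klrc1, which encode the CD94 and NKG2A receptor chains, had log2 fold changes of -2.39 (SE 0.33) and -1.88 (SE 0.18). Nkg7 had -1.54 (SE 0.14). Isg15, a ubiquitin-like interferon-induced protein gene, had 1.31 (SE 0.16), and Il9, the cytokine interleukin 9, had 1.99 (SE 0.27). In all, 122 of 14958 genes passed limma's test at an adjusted p under 0.05, of which 66 were higher and 56 lower, and 85 changed by at least 1.5-fold. An unadjusted p under 0.05 was reached by 2108 genes, against 748 expected by chance. Without the donor block only Adarb1 and Thy1 passed limma's test, so the calls of all other genes given here for ADAR2 WT rest on that pairing; edgeR without the block called 1 gene and DESeq2 42, while DESeq2 with it called 211. Leaving out the ADAR2 WT library of donor A or B gave 1 and 6 genes, the empty-vector library of donor A or B 66 and 913, and the ADAR2 E396A library of donor A or B 941 and 1217.

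The 10 genes that rose most with ADAR2 WT, by the rule fixed beforehand, included Gphb5 (log2 fold change 2.76, SE 0.47), Myh11, a smooth muscle myosin heavy chain gene (2.30, SE 0.25), Mmp10, a matrix metalloproteinase gene (1.35, SE 0.24), C1s2 (1.30, SE 0.19) and Egfr, the epidermal growth factor receptor gene (1.12, SE 0.15). Their limma adjusted p lay between 0.0125 for Myh11 and 0.0486 for Mmp10. The 10 that fell most included Bst1 (-2.23, SE 0.16), Adamts14 (-2.11, SE 0.28), the chemokine gene Ccl9 (-1.83, SE 0.25), Styk1 (-1.53, SE 0.24), Ociad2 (-1.45, SE 0.21), Trib2 (-1.44, SE 0.23) and Tgfb3, a TGF-beta family cytokine gene (-1.41, SE 0.24). Their limma adjusted p lay between 0.0017 for Bst1 and 0.0436 for Tgfb3.

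Of 33 measured interferon-stimulated genes, 10 rose with ADAR2 WT and none fell, and 23 rose when adjusted over the list alone. The fold change was positive for 31, with a median log2 fold change of 0.48. Irf7, a transcription factor of the interferon response, rose by 0.98 (SE 0.10, limma adjusted p = 0.0125), Ifi27l2a by 0.67 (SE 0.08, limma adjusted p = 0.0193) and Mx2 by 1.13 (SE 0.17, limma adjusted p = 0.0362). Mx2 is annotated as a polymorphic pseudogene. The list was higher by limma's camera test (adjusted p = 2.16e-14). That call was lost with an estimated correlation (adjusted p = 0.802).

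Of 16 genes of the Th1 and cytotoxic list, Nkg7 fell and the others did not pass; 6 fell when adjusted over the list alone. Of 5 measured CD8 and NK cell markers, Klrc1, Klrd1 and Klrk1 fell, the last by 1.38 (SE 0.23, limma adjusted p = 0.0416), and 3 passed when adjusted over the list alone. These 3 receptor genes lie near each other on chromosome 6. Cd8b1 had a log2 fold change of 0.21 (SE 0.16) and Cd8a -0.47 (SE 0.55), neither of which passed. By camera the lists were lower (adjusted p = 0.000546 and 0.0256). Neither call held with an estimated correlation (adjusted p = 0.802 for each). That of the CD8 and NK cell list was also lost without the empty-vector library of donor B (adjusted p = 0.166) or the ADAR2 E396A library of donor A (adjusted p = 0.053), on ranks of the statistic (0.117), with genes of a mean of at least 100 normalized counts (0.0605) and at an inter-gene correlation of 0.05 (0.0567).

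Of 10 measured mitochondrial transcripts, 5 rose, and 9 rose when adjusted over the list alone. The ribosomal RNA genes mt-Rnr1 and mt-Rnr2 rose by 0.90 (SE 0.06) and 0.56 (SE 0.06), and mt-Nd2 and mt-Nd4, which encode subunits of respiratory complex I, by 0.88 (SE 0.11) and 0.53 (SE 0.08). The list was higher by camera (adjusted p = 2.27e-07), but not with an estimated correlation (adjusted p = 0.615). The estimate was -0.075, below the preset 0.01, so correlation between these genes did not cause that loss. Mitochondrial ribosomal RNA made up 0.213% and 0.185% of reads in the empty-vector libraries, 0.328% and 0.278% with ADAR2 WT, and 0.299% and 0.239% with ADAR2 E396A (donors A and B).

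No single gene passed over all genes in the cell cycle, the unfolded protein and integrated stress response, or the ribosomal protein list. Adjusted over the list alone, 4 of 30, 9 of 18 and 0 of 26 passed. Camera called the first list higher (adjusted p = 4.29e-06), with a median log2 fold change of 0.20. It called the stress response list higher (adjusted p = 5.06e-05), with all 18 members positive, and the ribosomal protein list lower (adjusted p = 0.0101), with 24 of 26 members negative. The Th2 list was higher (adjusted p = 0.0256), with Ccr4, a chemokine receptor gene, rising by 0.43 (SE 0.07, limma adjusted p = 0.0426) as the 1 member that passed, also when adjusted over the list alone. None of these calls held with an estimated correlation (adjusted p = 0.802, 0.802, 0.83 and 0.802). Camera's adjusted p without the empty-vector library of donor A was 0.107 for the stress response, 0.198 for the ribosomal protein and 0.533 for the Th2 list; without the ADAR2 WT library of donor B it was 0.237 and 0.146 for the last 2, and without that of donor A 0.108 for the cell cycle list. The ribosomal protein call was also lost without the donor block (adjusted p = 0.128), without the filter (0.0812) and on log2 fold changes in place of the statistic (0.236), and it and the Th2 call at an inter-gene correlation of 0.05 (0.0704 for each).

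The Th17 cytokine genes Il17a and Il17f did not pass with ADAR2 WT. Il17a had a log2 fold change of 1.19 (SE 0.24, limma adjusted p = 0.0803) and Il17f 0.57 (SE 0.31, limma adjusted p = 0.449). Foxp3, Ifng and Tbx21 had 0.11, -0.72 and -0.23 (limma adjusted p = 0.94, 0.283 and 0.424). In the empty-vector libraries Il17a was at 2437 normalized counts in donor A and 9279 in donor B.

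Members of other lists that passed with ADAR2 WT were Zfr, an RNA-binding zinc finger protein gene (log2 fold change 0.72, SE 0.06, limma adjusted p = 0.0049), Pmepa1 (0.45, SE 0.07, limma adjusted p = 0.0352), Gadd45a, a growth arrest and DNA damage gene (1.14, SE 0.18, limma adjusted p = 0.0371), and Irf8, an interferon regulatory factor gene (-0.73, SE 0.12, limma adjusted p = 0.0416).

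ADAR2 E396A was compared with the empty vector to find what the protein changed without its deaminase activity. Adarb1 rose, as given above, and Thy1 (ENSMUSG00000032011.5, chromosome 9, 44043384 to 44048579), which encodes a surface glycoprotein of T cells, fell by 0.99 (SE 0.07, limma adjusted p = 0.0021). No other of the 14958 genes passed, and 582 had an unadjusted p under 0.05, against 748 expected by chance. Across genes, the ADAR2 E396A changes of donors A and B were negatively correlated (r = -0.253). With replicates that differ in this way, few calls do not show that the construct changed little. The other tools with the donor block called 2 to 3 genes (edgeR) and 7 (DESeq2). Zfr was among them by edgeR with TMM and by DESeq2. Thy1 also fell with ADAR2 WT, by 1.19 (SE 0.07, limma adjusted p = 0.000471). It was at 24304 and 21422 normalized counts with the empty vector, 10400 and 9596 with ADAR2 WT, and 11407 and 11528 with ADAR2 E396A. Without the donor block only Adarb1 passed limma's test, and Thy1 did not. Leaving out the ADAR2 E396A library of donor A or B gave 127 and 120 genes, the empty-vector library of donor A or B 8 and 7, and the ADAR2 WT library of donor A 1, which was Adarb1.

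Camera called the interferon-stimulated list higher with ADAR2 E396A (adjusted p = 1.38e-07), with a median log2 fold change of 0.21. None of its 33 members passed over all genes, and 2 did when adjusted over the list alone. The mitochondrial list was higher (adjusted p = 3.22e-06, median 0.27, 3 of 10 when adjusted over the list alone) and the cell cycle list was higher (adjusted p = 0.000122, median 0.13, 0 of 30 when adjusted over the list alone). The T cell activation list was lower (adjusted p = 0.0474, median -0.12, 0 of 21 when adjusted over the list alone). None held with an estimated correlation (adjusted p = 0.875, 0.729, 0.875 and 0.875). Without the empty-vector library of donor B the interferon-stimulated and mitochondrial calls were lost (adjusted p = 0.231 and 0.0804), and without that of donor A or the ADAR2 E396A library of donor B the cell cycle call was lost (adjusted p = 0.935 and 0.0993). The T cell activation call was lost without the donor block (adjusted p = 0.337) and without each library other than the ADAR2 E396A library of donor A: without empty vector of donor A or B (adjusted p = 0.127 and 0.182), ADAR2 WT of donor A or B (0.0587 and 0.0611) and ADAR2 E396A of donor B (0.343), as well as without the filter (0.114) and at an inter-gene correlation of 0.05 (0.23). Il17a, Il17f, Foxp3, Ifng and Tbx21 had log2 fold changes of 0.54, 0.38, -0.21, 0.09 and -0.25, each with a limma adjusted p of 0.999.

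The direct contrast of ADAR2 WT with ADAR2 E396A asked what depended on the catalytic residue, as far as the constructs were expressed alike. Adarb1 was higher with ADAR2 WT in both donors, by 0.29 (SE 0.07) on the log2 scale. An effect of that difference cannot be separated from one of the residue. By limma, 10 genes passed, 2 higher and 8 lower with ADAR2 WT. Il9 was higher by 2.13 (SE 0.27, adjusted p = 0.0481). Lower were Bst1 (-1.91, SE 0.16), Cd93, a surface C-type lectin gene (-1.79, SE 0.14), Klrc1 (-1.75, SE 0.18), Ly6c1 (-1.54, SE 0.18), Nkg7 (-1.22, SE 0.14), B4galnt4 (-1.01, SE 0.09), Ifitm1 (-1.0, SE 0.11) and Mctp2 (-0.98, SE 0.11). Their limma adjusted p lay between 0.0116 for Cd93 and Bst1 and 0.0269 for the last of them. The tenth gene, Gm7860, is a processed pseudogene with a log2 difference of 2.23, so it is uncertain which gene its reads came from. It was named after its value was seen. With the block, 1853 genes had an unadjusted p under 0.05, and edgeR called 10 genes and DESeq2 110. Without the donor block 0 genes passed limma's test (732 at an unadjusted p under 0.05), edgeR called 0 and DESeq2 7. Leaving out the ADAR2 WT library of donor A or B gave 0 (686 at an unadjusted p under 0.05) and 2 genes by limma, the empty-vector library of donor A or B 467 and 425, and the ADAR2 E396A library of donor A or B 844 and 217.

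For the interferon-stimulated list the difference between constructs was positive by camera (adjusted p = 6.15e-08, median log2 difference 0.28), with 0 of 33 members passing over all genes and 17 when adjusted over the list alone. The stress response list was also higher (adjusted p = 1.01e-05; 10 of 18 when adjusted over the list alone), as were the mitochondrial list (adjusted p = 0.00149; 6 of 10) and the Th2 list (adjusted p = 0.00374; 7 of 11). The ribosomal protein (adjusted p = 0.00149; 0 of 26), Th1 and cytotoxic (adjusted p = 0.00992; 5 of 16) and CD8 and NK cell lists (adjusted p = 0.0381; 3 of 5) were lower, each count being that adjusted over the list alone. With an estimated correlation none passed (adjusted p between 0.751 and 0.834). The Th2 list had medians of 0.79 and -1.02 in the ADAR2 E396A libraries of donors A and B, and its call was lost without the ADAR2 E396A library of donor B (adjusted p = 0.681) or the ADAR2 WT library of donor B (0.0627). The Th1 and cytotoxic call was lost without the ADAR2 WT (adjusted p = 0.141) or ADAR2 E396A library of donor A (0.153), the CD8 and NK cell call without the ADAR2 E396A library of donor A or B (0.19 and 0.0798), and the ribosomal protein call without the donor block (0.0638), the ADAR2 WT library of donor B (0.22) or the ADAR2 E396A library of donor B (0.259). The CD8 and NK cell call was also lost on ranks of the statistic (adjusted p = 0.159), with genes of a mean of at least 100 (0.087) and with size factors from nuclear protein-coding genes (0.0542). At an inter-gene correlation of 0.05 it and the Th1 and cytotoxic call were lost (0.0614 and 0.0551), without the filter the mitochondrial and ribosomal protein calls (0.0767 for each), and on log2 fold changes the ribosomal protein call (0.134).

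**Figure D2:**
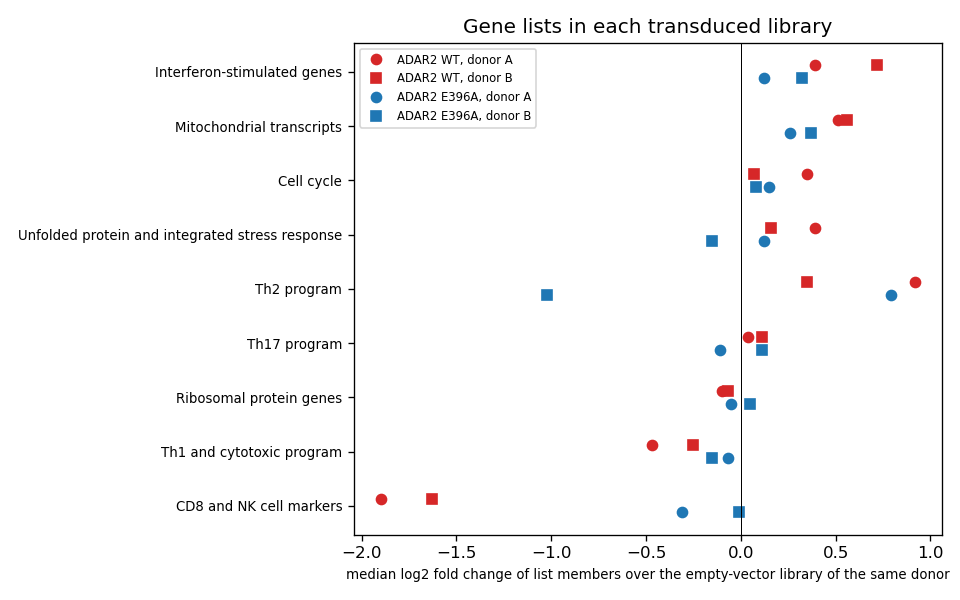
Median log2 fold change (x axis) of the members of 9 gene lists (y axis) in each transduced library over the empty-vector library of the same donor, with a point per construct and donor. The interferon-stimulated list lies at 0.39 and 0.72 with ADAR2 WT and at 0.12 and 0.32 with ADAR2 E396A, and the Th2 list at 0.79 and -1.02 in the ADAR2 E396A libraries.

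The changes of the constructs were then set against each other. Adarb1 and Thy1 passed in both comparisons with the same direction, where unchanged groups simulated against the same controls shared 0.54 genes on average (0 to 5) and independent lists would share 0.0044 higher and 0.0037 lower genes. Across 10770 genes the fold changes of the constructs had a Pearson r of 0.359 and a Spearman rho of 0.383, against simulated means of 0.502 and 0.473. Their covariance was 0.0132, against 0.012 simulated (0.0111 to 0.0131). Genes are not independent replicates, and the control libraries are shared. Taken across donors, so that no library is shared, ADAR2 WT in donor A against ADAR2 E396A in donor B had r = -0.291 and ADAR2 WT in donor B against ADAR2 E396A in donor A r = 0.286, where simulated unchanged groups gave -0.027 to 0.029 and -0.031 to 0.027. These signs are opposite, so the r of 0.359 is not taken as a change shared by the constructs. Across donors in the same way, ADAR2 WT in donor A against donor B had r = 0.553. ADAR2 E396A in donor A against donor B had r = -0.253. Simulated unchanged groups gave -0.021 to 0.034 and -0.025 to 0.025. The simulation draws each gene independently, with no variation that moves many genes of a library together. An r outside its ranges therefore does not by itself show a change by a construct. Leaving out the ADAR2 E396A library of donor A moved the correlation between constructs to -0.008, and leaving out the empty-vector library of donor B moved it to 0.726. The count of genes shared by both comparisons was 32 and 81 without the ADAR2 E396A library of donor A or B, 4 and 7 without the empty-vector library of donor A or B, 1 without the ADAR2 WT library of donor A and 1 without the donor block.

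In the authors' deposited table for ADAR2 WT, 196 genes had an adjusted p under 0.05, 97 of them higher with the construct and 99 lower. In the authors' deposited table for ADAR2 E396A, 2 genes did. Of the 122 genes called here, 97 were also called in the authors' deposited table, all in the same direction. Both sets of calls come from the same reads, and the donor pairing was read from the authors' statistics. The overlap is therefore no independent check.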

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

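The tests of explanations in this part were chosen after the patterns were seen, and those on GC content and gene length after related trends over all genes had been seen. The direct contrast of the constructs singled out 10 genes whose change with ADAR2 WT differed from that with ADAR2 E396A by limma at an adjusted p under 0.05: Il9 (log2 difference 2.13), Gm7860 (2.23), Bst1 (-1.91), Cd93 (-1.79), Klrc1 (-1.75), Ly6c1 (-1.54), Nkg7 (-1.22), B4galnt4 (-1.01), Ifitm1 (-1.0) and Mctp2 (-0.98). Without the donor block 0 genes passed limma's test.

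The first pattern weighed is the rise of interferon-stimulated genes with ADAR2 WT, a median log2 fold change of 0.48 over 33 genes. Removing the linear trend of fold change with GC content and gene length, fitted over all genes, left a median of 0.51 (SE 0.09). This argues only against that linear trend as the cause, and effects of GC content or length of another form were not tested. Removing the component shared with the difference between the ADAR2 E396A libraries of the donors left 0.55 (SE 0.08), which argues against that axis of variation. Both SEs are across the 33 genes taken as independent, and do not measure variation between libraries. Camera called the list higher with ADAR2 E396A (adjusted p = 1.38e-07, median 0.21), which a response to deaminase activity alone does not predict, and higher with ADAR2 WT than with ADAR2 E396A (adjusted p = 6.15e-08, median difference 0.28), which goes the way of a response to activity; neither call held with an estimated correlation (adjusted p = 0.875 and 0.751), and the first was lost without the empty-vector library of donor B (0.231). Responses to activity and to the protein stay open beside culture or transduction differences between groups, which may contribute and which the design cannot separate with 2 libraries each.

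The second pattern is the fall of Klrc1, Klrd1, Klrk1 and Nkg7 with ADAR2 WT, with a median of -1.71. It stayed at -1.73 (SE 0.29) with the GC and length trend removed and at -1.61 (SE 0.23) with the ADAR2 E396A axis removed. Both of these SEs are across the 4 genes, which were picked because they passed, and do not measure variation between libraries. Among Ncr1, Klrb1c, Klra8, Tyrobp and Fcer1g, a list of NK cell markers written for this test, the highest level in an empty-vector library was 0.396% of that of Klrc1, which argues against NK cells as the source. For CD8 T cells, Cd8b1 had a log2 fold change of 0.21 (SE 0.16) but Cd8a was too variable (SE 0.55), so fewer CD8 T cells, which a start from naive CD4 T cells should exclude, and a change within CD4 T cells cannot be told apart.

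The third pattern is the fall of Thy1 with both constructs. Under 3 other scalings the log2 fold change nearest 0 was -0.96. A scaling moves all genes of a library together. The median log2 fold change over all genes was -0.002 with ADAR2 WT and -0.009 with ADAR2 E396A. These scalings could thus hardly have removed the fall, so the test itself is only weak evidence against scaling. A scaling leaves the distance of Thy1 from that median unchanged, and Thy1 was at -0.99 (SE 0.07) or lower with both constructs. These values argue against scaling as the cause of a fall relative to the other genes. A Thy1 marker carried by the vector and expressed more from the empty one is a candidate explanation that was not tested. The labels name no marker, and reads over the gene were not analysed here. A fall of the cells' own Thy1 also stays open.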

How the results depend on the processing

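The alternatives with TMM in limma or edgeR, with size factors from nuclear protein-coding genes, with an estimated correlation and with other tools without the donor block were chosen after the data were examined; all others were planned. The donor block decides most calls. The pairing was read from the authors' deposited statistics. Without the replicate block limma called 2 genes with ADAR2 WT, 1 with ADAR2 E396A and 0 between constructs in place of 122, 2 and 10, with 1 shared by both constructs in place of 2. Without it edgeR called 1, 1 and 0 and DESeq2 42, 3 and 7. Of 61 gene results, 40 lost their call without the block and none changed sign. The 61 include genes named whatever their values, which had no call to lose. Among the called ones, only the results of Adarb1 against the empty vector kept their call. The list counts were 7, 3 and 6 in place of 8, 4 and 7.

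In the same order of comparisons, no filter gave 220, 5 and 102 genes (5 shared) and DESeq2 211, 7 and 110 (7 shared), with 13, 12 and 11 lists. A mean of at least 100 gave 36 and 3 genes with ADAR2 WT and between constructs, limma with TMM 39 between constructs, and an adjusted p under 0.01 10 and 0 and under 0.1 267 and 56. An absolute log2 fold change of at least 1 gave 40 genes with ADAR2 WT and 1 with ADAR2 E396A. Only the 4 libraries compared gave 1237, 1 and 194 genes (1 shared). Lists numbered 7 with ADAR2 E396A by edgeR with either scaling, 5 with ADAR2 WT at an inter-gene correlation of 0.05, and 0, 0 and 0 with an estimated correlation. The cause of these differences was not tested, apart from the thresholds and filters, which change the genes counted by construction. The estimated correlation also leaves camera few degrees of freedom, as given above.

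Leaving out 1 library, the lone library being assumed to vary like the others, gave 1 to 1217 genes with ADAR2 WT, 1 to 127 with ADAR2 E396A and 0 to 844 between constructs, 1 to 81 shared genes, 5 to 8, 1 to 6 and 4 to 8 lists, and a correlation of -0.008 to 0.726; the cause was not tested. In each such fit the lone library of a group is fitted exactly, so the variance came only from the groups that kept both libraries. Under these fits 13 values of single genes changed sign, all of genes that did not pass in the fit of all 6 libraries. Their log2 fold changes ranged, for ADAR2 WT, from -0.45 to 0.67 for Foxp3. For ADAR2 E396A they ranged from -0.017 to 1.09 for Il17a, -0.37 to 1.14 for Il17f, -0.77 to 0.35 for Foxp3 and -0.43 to 0.61 for Ifng. Between constructs they ranged from -0.57 to 0.94 for Il17f, -0.007 to 0.65 for Foxp3 and -0.20 to 0.25 for Tbx21. With 2 libraries per group, the self-test on simulated counts for ADAR2 WT recovered 70.3% of 1.5-fold changes, so smaller changes can be missed. That share holds for genes with a mean of at least 50 reads, simulated independently.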

Other observations

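The list tests here were planned, and the comparison of the 120 genes and the donor differences were chosen after the data were examined. The ADAR family list had 2 measured members, Adarb1 and Adar. Adjusted over this list alone, 2 were higher with ADAR2 WT than with empty vector and 2 than with ADAR2 E396A. With ADAR2 E396A against empty vector 1 was higher. Of the lists with a camera test that the report does not call in any comparison, none had a member beyond those named above passing over all genes with ADAR2 WT. With ADAR2 WT the camera adjusted p was 0.647 for the Th17 list (median log2 fold change 0.06), 0.796 for Treg (0.06), 0.796 for recoding targets of editing (0.01), 0.485 for double-stranded RNA binding and paraspeckle (0.04), 0.37 for TGF-beta (-0.09), 0.054 for IL-6 and STAT3 (-0.18), 0.06 for naive and memory T cell (-0.15), 0.485 for glycolysis and hypoxia (-0.04), 0.126 for cholesterol synthesis (0.07), 0.903 for p53 (-0.04) and 0.796 for T cell activation (0.02). Adjusted over the list alone, 3 members rose and 1 fell in the Th17 list, 1 rose and 6 fell in the IL-6 and STAT3 list, 2 rose and 1 fell in the double-stranded RNA list, 4 fell in the T cell activation list, 1 fell in the naive and memory list, 1 rose in each of the TGF-beta and p53 lists, and 0 passed in the Treg, recoding, glycolysis and cholesterol lists. The mean differed in sign from the median for Treg (-0.03 against 0.06), T cell activation (-0.03 against 0.02), p53 (0.005 against -0.04) and myeloid markers (0.21 against -0.004). By fry, which tests whether a list's genes move 1 way on balance, no list passed: the smallest adjusted p was 0.126 with ADAR2 WT, 0.287 with ADAR2 E396A and 0.243 between constructs. By fry's mixed test, which counts genes moving either way, the mitochondrial list passed with ADAR2 WT, with ADAR2 E396A and between constructs (adjusted p = 0.00287, 0.000833 and 0.0306), the double-stranded RNA list with ADAR2 WT and ADAR2 E396A (0.049 and 0.000833) and the interferon-stimulated list with ADAR2 WT (0.049). Among markers of other cells the camera adjusted p with ADAR2 WT was 0.647 for B cells, 0.796 for myeloid cells and 0.503 for gamma-delta T cells. Of 6 erythroid markers 1 was measured, and of 5 stromal markers 0.

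Zfr had log2 fold changes of 0.72 with ADAR2 WT and 0.57 with ADAR2 E396A. The latter did not pass in the main fit, by edgeR with median-of-ratios factors, with other pseudocounts or by limma without the block. It passed with TMM in limma or edgeR, with size factors from nuclear protein-coding genes and without the filter. DESeq2 also called it, with and without the block. Cd93 had -1.26 with ADAR2 WT and 0.53 with ADAR2 E396A. The 5.8S ribosomal RNA gene n-R5-8s1 had 3.87 with ADAR2 WT at a mean of 27.4 normalized counts. Gm26917 had -0.22 with ADAR2 WT.

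Of the 120 genes called with ADAR2 WT other than Adarb1 and Thy1, 101 had the same sign with ADAR2 E396A, with a median ratio of the log2 changes of 0.30 (quartiles 0.11 and 0.42). These genes were chosen on ADAR2 WT libraries and both changes share controls, so the ratio is no test of a difference. The difference between the changes of the ADAR2 E396A libraries of donors A and B correlated with the mean ADAR2 WT change across genes (r = 0.425). Simulated unchanged groups gave -0.037 to 0.038. Genes were simulated independently, so this range leaves out variation that moves many genes of a library together.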
